A study of Mus musculus with 34 samples.

How the data were processed

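Ribosome-protected mRNA fragments (footprints, RPF) and RNA were sequenced from mouse hippocampus (strain C57BL/6N) of control mice and of mice taken 5, 10 or 30 min or 4 h after contextual fear conditioning, in which a foot shock is paired with a chamber. Each of the 5 groups had 3 replicates in RPF and 3 in RNA, which makes 15 libraries of each kind. Hippocampal primary culture and mouse embryonic stem cells (ESC, line A3-1, treated with a siRNA against luciferase) had 1 RPF and 1 RNA library each. Per the labels, tissue and cells were lysed in the presence of cycloheximide, which holds ribosomes on mRNA, and ribosome-bound mRNA was collected on gel filtration columns. Libraries were made with a small RNA library method. Whether replicates of a group come from separate mice is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

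Per the submitters' processing notes, reads were called with CASAVA 1.8.2 and aligned with Bowtie 1.1.1 to the mouse genome mm9. The unit of the deposited values, called signal here, is not named in the file headers. The signal values proved to be whole numbers of reads divided by 1 number per library: multiplied by that number, all values lay within 0.001 reads of a whole number. The meaning of the divisor, and whether gene length enters it, are not given in the sources used here, so a signal is compared between libraries for 1 gene and never between genes as an amount. The deposited mean columns equal the arithmetic means of the replicates, and the deposited log2 columns, per the file headers comparisons of a time with control, equal the log2 ratios of those means. How the authors counted reads that match several genes or either strand is not given in the sources used here, and genes with near-identical copies, such as ribosomal protein genes, are uncertain for that reason. Genes carry the symbols that the deposited tables pair with RefSeq identifiers; 2 symbols occur on 2 genes each. No coordinates are given, because the reference annotation at hand is of another genome build.

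The tissue tables list 11531 genes, that of the culture lists 10379 and that of ESC lists 11029. Depth was taken as the recovered reads on listed genes, which is part of a library. Tissue RPF libraries held 14240563 to 30480009 such reads and tissue RNA libraries 16814796 to 25515210. The culture held 18771379 (RPF) and 7282564 (RNA), and ESC held 65147288 and 16686790. The median gene held 416 to 891 reads in tissue RPF libraries and 517 to 766 in tissue RNA libraries. The smallest number of reads listed was 3. The most abundant gene took 1.19 to 2.55% of the reads in tissue RPF libraries and 12.0 to 15.5% in tissue RNA libraries. Intervals given for single libraries cover counting error only, since PCR copies are not independent molecules.

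The tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. That design named no test for values of this unit, so the test written for normalised values was used: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(signal + 1), with all 5 groups in 1 model and no block, for genes with a mean of at least 1 over the 15 libraries. This left 7898 genes in RPF and 8061 in RNA. In RPF and RNA, changes on this scale understate the fold change of genes with low values, so group means are printed beside them. Each time was compared with control, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and a moderated F-test asked whether any time differed. Translational efficiency (TE), the footprint signal relative to the RNA signal, was compared as the interaction of both kinds of library in 1 model of 30 libraries, over 7103 genes. Values are printed as the mean ± SD of the signal with n = 3, and log2 changes with the standard error (SE) of the model.

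A total of 38 gene lists, covering activity-regulated genes, translation, synapses, metabolism, cell types, neighbouring tissues and controls, were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, and adjusted over lists by Benjamini-Hochberg. 37 lists had a member past the filter. The call under a correlation estimated from the residuals is given beside each list. Counts adjusted over the list alone come from the same gene tests. Baseline TE was log2((RPF + 1)/(RNA + 1)) minus the median gene of the same sample. A list's median was ranked among 10000 random lists of the same size matched on RNA signal.

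Named genes were the 8 per direction with the largest change past the threshold and without overlap between the groups (5 for TE). Where fewer than 3 passed in a direction, the 3 with the smallest unadjusted p were taken and are described as not past the threshold. A fixed set of activity-regulated and stress-regulated genes, up to 4 members of each called list and the highest and lowest members of baseline lists were named too. Genes under the filter, and those named from fits with the block or without a filter, were chosen after their values were seen. Some genes that the rule names are not reported here, though they enter the counts.

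Replicate numbers paired the samples. Deviations from the group means correlated between every 2 libraries of the same number (lowest r across genes 0.402 in RPF and 0.268 in RNA, 30 pairs each), whereas the highest r between different numbers was 0.259 and 0.124. All 15 libraries of each kind matched their own number best, and the first principal component held 58.8% and 55.8% of the variance, of which 99.1% and 98.8% lay between numbers. What a number shares is not given in the sources used here. Results of the fit with the replicate number as a block are therefore printed wherever they change a call.

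The alternatives fixed in advance were a pseudocount of 0.1 or 0.5, a filter at 5 or none, centring on the median gene, scaling by trimmed means (trim 0.3 and 0.05), limma with a robust prior and no trend, a fit of only the groups compared, the replicate block, RPF and RNA pairs as the block for TE, the estimated correlation and each library left out. Alternatives chosen after seeing the data were limma's voom on the recovered whole reads, the block combined with voom, no filter, a pseudocount of 0.1, median centring, the estimated correlation, a choroid plexus covariate or 1 replicate number left out, and lists with at least 3 measured members. Differences between times, exact tests of list scores, tests of replicate numbers and correlations with exchanged labels were also chosen after seeing the data.

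The models were tested on simulated reads for the RPF comparison of 30 min with control (7894 genes). Without a block, 64% of the genes changed 1.5-fold, 95.8% of those changed 2-fold and 95.7% of those changed 3-fold were called, with 0 false among 128 calls, which also hold a smaller fold that was called in 10%. With the block, 94, 100 and 100% were called, 74% at the smallest fold, with 12 false among 191. For RNA at 30 min (8045 genes) the shares without a block were 74, 95.7 and 100%, and with it 98, 100 and 100%, with 9 false among 190. For TE at 30 min (7100 genes) they were 53.5, 93.5 and 92.9% without a block and 88.4, 100 and 97.6% with it. The deposited mean and log2 columns were not used further.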

Results

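Ribosome footprints and RNA were measured in the mouse hippocampus before and after contextual fear conditioning, a form of learning that depends on this region. Footprints count ribosomes on each mRNA, and set against RNA they show how much of a change in protein synthesis exceeds the change in mRNA. The tissue series had 5 groups of 3 replicates, taken as control or 5, 10 or 30 min or 4 h after conditioning, with 15 RPF and 15 RNA libraries. Hippocampal primary culture and ESC, which are pluripotent embryo-derived cells, added 1 library of each kind apiece, so those values have no replicates.

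The replicate number, not the time after conditioning, went with most of the variation between tissue libraries. The list that varied most was the choroid plexus, the secretory epithelium of the ventricles that borders the hippocampus. Ttr, which encodes the thyroxine carrier transthyretin, was abundant in replicates 1 and 2 of every group and far lower in 3. Its mean RPF signal was 1130, 1090 and 147 in replicates 1 to 3, over 5 groups, and that of Enpp2 405, 244 and 76.8. Outside that list, Gm20594 ran at 83.3, 306 and 529 and Lrp1 at 109, 52.6 and 42.8. By limma, with Benjamini-Hochberg adjustment, 5772 of 7898 genes in RPF (73.1%) and 5279 of 8061 in RNA (65.5%) differed between numbers. The mean log2(signal + 1) of the immediate-early list ranged over 0.042 between numbers in RPF and 0.020 in RNA. This was not particular to that list: CA1 genes ranged over 0.0092 in RPF and striatum genes over 0.0146 in RNA.

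Footprints at 5 min were compared with control to ask which mRNAs gained or lost ribosomes within minutes of conditioning. Genes of the proteasome, the protease that degrades ubiquitin-tagged proteins, carried fewer footprints as a list, and genes of inhibitory synapses, microglia, potassium channels and CA1 pyramidal neurons more. All 5 calls were lost with an estimated correlation (adjusted p = 0.677 to 0.816). No single gene passed the test. Nrsn1, which encodes a vesicle membrane protein of neurites, was lower in all replicates but did not pass.

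At 5 min, 0 of 7898 genes passed by limma (smallest Benjamini-Hochberg adjusted p = 1), with 51 at an unadjusted p under 0.05. The voom and robust fits gave 0, and the replicate block gave 0 as well (smallest adjusted p = 0.324). Nrsn1 went from 3.27 ± 0.435 to 2.49 ± 0.214 (SD, n = 3), a log2 change of -0.29 (SE 0.11, limma adjusted p = 1), lower in 3 of 3 replicate numbers. The smallest unadjusted p-values among lower genes, none past the threshold, belonged to the kinase gene Mapk6 (1.49 ± 0.107 to 1.16 ± 0.0435), the transcription elongation kinase gene Cdk9 (3.33 ± 0.0853 to 2.85 ± 0.1) and the histone deacetylase gene Hdac5 (4.41 ± 0.104 to 3.78 ± 0.148). Among higher genes they belonged to the deubiquitinase gene Usp42 (1.13 ± 0.0938 to 1.38 ± 0.0339), the sphingomyelinase gene Smpd1 (14.5 ± 0.945 to 17.1 ± 0.744) and Reep1, which shapes endoplasmic reticulum (7.24 ± 0.559 to 8.32 ± 0.373).

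By camera, 5 of 37 lists were called at 5 min (3 without control replicate 2, 11 without control replicate 1), and 0 with an estimated correlation. The proteasome list was lower in 29 of 30 genes (median log2 change -0.08, camera adjusted p = 5.06e-08), and adjusted p = 0.816 with an estimated correlation. Psma6 and Psmd14, subunits of its core and its lid, went from 7.75 ± 0.334 to 6.85 ± 0.32 and from 6.75 ± 0.307 to 5.95 ± 0.514. It was the only list called without any 1 of the 6 libraries (largest adjusted p = 0.000312, without control replicate 3). GABA receptor and inhibitory synapse genes, such as the GABA receptor subunit gene Gabra5 (18.9 ± 2.1 to 20.8 ± 1.88), had a median of 0.08 (adjusted p = 0.00216). Without control replicate 2 that became -0.02 (adjusted p = 0.914), and without 5 min replicate 1 adjusted p = 0.395. Microglial genes, among them the protease gene Ctss (8.87 ± 2.27 to 9.88 ± 1.93) and the growth factor receptor gene Csf1r (13 ± 3.03 to 14.4 ± 3.36), had a median of 0.09 (adjusted p = 0.00334) and lost the call without the same libraries. Potassium channel genes had a median of 0.05 (adjusted p = 0.00334), with adjusted p = 0.116 without 5 min replicate 1. CA1 genes, such as the secreted-factor gene Nov (34.1 ± 3.31 to 38.7 ± 0.841), had a median of 0.03 (adjusted p = 0.0427) and lost the call in 5 of the 6 omissions, all but that of control replicate 3. Adjusted p = 0.816 with an estimated correlation for the inhibitory, microglial and potassium channel lists, and 0.677 for CA1. The block called 8 lists, adding late-response genes (adjusted p = 0.0455), oxidative phosphorylation (adjusted p = 0.0109) and ribosomal protein genes (adjusted p = 0.00593), the last 2 lower, all 3 lost with an estimated correlation (adjusted p = 0.725).

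By 10 min the question is whether the genomic response to neuronal activity has reached the ribosomes. Immediate-early genes, which neurons transcribe within minutes of firing, carried more footprints as a list, a call lost with an estimated correlation (adjusted p = 0.165). With low values kept, the neuronal activity regulator gene Npas4 passed, and with the block also Arc, whose protein removes AMPA receptors from synapses, and the AP-1 subunit gene Junb. Glucocorticoid-responsive, dentate granule cell, glial and potassium channel genes also carried more footprints, and proteasome and protein kinase A pathway genes fewer. These calls too were lost with an estimated correlation (adjusted p = 0.404 to 0.692), and each was lost without at least 1 library.

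Among 7898 genes, limma called 0 at 10 min (smallest adjusted p = 1), with 26 at an unadjusted p under 0.05. The robust and voom fits gave 0. With the block it was 0 too (smallest adjusted p = 0.0565), for Arc and Junb. Voom with the block called both of them. Arc went from 4.51 ± 0.697 to 6.56 ± 1.04 (log2 change 0.46) and Junb from 2.54 ± 0.35 to 3.54 ± 0.586 (0.35), both higher in 3 of 3 numbers, and Egr1 from 6.91 ± 0.651 to 8.69 ± 0.535. With no filter on low values, Npas4 passed (0.176 ± 0.0512 to 0.741 ± 0.092, 4.2-fold, limma adjusted p = 0.00186). Once the block was added, 5 genes passed: Npas4 (adjusted p = 3.47e-07), Arc, Junb, the AP-1 gene Fos (0.398 ± 0.0405 to 0.875 ± 0.232, adjusted p = 0.00136) and the antiproliferative gene Btg2 (0.396 ± 0.0408 to 0.62 ± 0.0763, adjusted p = 0.0173). Genes with the smallest unadjusted p among lower ones, not past the threshold, were Mapk6 (1.49 ± 0.107 to 1.19 ± 0.0604), the endothelial tight junction gene Cldn5 (1.32 ± 0.122 to 1.03 ± 0.0892) and Ccdc91, which encodes a Golgi trafficking protein (1.77 ± 0.13 to 1.5 ± 0.0359).

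Camera called 12 of 37 lists at 10 min, a count of 7 without control replicate 2 and of 0 with an estimated correlation. Immediate-early genes were higher in 14 of 21 (mean log2 change 0.08, median 0.019, adjusted p = 7.04e-06), and adjusted p = 0.165 with an estimated correlation. It alone was called in all 6 omissions (largest adjusted p = 0.0254, without 10 min replicate 2). Of its genes 3 passed adjusted over the list alone, against 0 over all genes. Glucocorticoid-responsive genes had a median of 0.07 (adjusted p = 0.00494), among them the kinase gene Sgk1 (6.32 ± 0.97 to 7.84 ± 0.26) and the anti-inflammatory regulator gene Tsc22d3 (3.49 ± 0.361 to 3.83 ± 0.255). Dentate granule cell genes had a median of 0.07 (adjusted p = 0.00979), oligodendrocyte genes 0.07 (0.00116), microglial genes 0.06 (0.00494), CA1 genes 0.08 (0.0258), astrocyte genes 0.05 (0.0321) and potassium channel genes 0.03 (0.00979). The myelin tight junction gene Cldn11 went from 27.2 ± 1.4 to 31.2 ± 1.57. Ribosomal protein genes were higher in 58 of 70 (median 0.04, adjusted p = 0.00102). Lower lists were the proteasome (-0.04, 0.00382), the protein kinase A and CREB pathway (-0.03, 0.00494), with the cAMP phosphodiesterase gene Pde4d (2.26 ± 0.133 to 2 ± 0.144), and endothelial cells and pericytes (-0.04, 0.0481). For these 11 lists adjusted p = 0.404 to 0.889 with an estimated correlation. Each lost its call without at least 1 library: leaving out control replicate 1, 2 or 3 ended 6, 7 and 4 of the 12 calls, and leaving out 10 min replicate 1, 2 or 3 ended 6, 5 and 7. Without 10 min replicate 3 the call of ribosomal protein genes reversed (median -0.05).

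The 30 min footprints show whether the mRNAs of activity-regulated genes are being translated while their proteins would be made. Arc, Junb, the zinc finger transcription factor gene Egr1 and the orphan nuclear receptor gene Nr4a1 carried more footprints by the fit with the block, and the immediate-early list rose as a whole. Fos and Fosb, low in signal, followed the same course. Glucocorticoid-responsive genes were higher as a list, and choroid plexus genes lower, both calls lost with an estimated correlation (adjusted p = 0.1 and 0.672).

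At 30 min, limma without a block called 0 of 7898 genes (20 at an unadjusted p under 0.05; smallest Benjamini-Hochberg adjusted p = 0.207, for Arc), and the voom and robust fits gave 0. With the replicate block 4 genes rose and 0 fell, and voom with the block called 4. Arc went from 4.51 ± 0.697 to 7.94 ± 0.331 (log2 change 0.70, SE 0.12, fold 1.76; unadjusted p = 5.25e-05 by limma, adjusted p = 0.00019 with the block). Egr1 went from 6.91 ± 0.651 to 9.86 ± 0.506, Nr4a1 from 1.78 ± 0.154 to 3.15 ± 0.125 and Junb from 2.54 ± 0.35 to 3.77 ± 0.364 (log2 changes 0.46, 0.58 and 0.43, adjusted p = 0.00246 each with the block). All 4 were higher in 3 of 3 numbers. Without replicate number 1 the blocked adjusted p was 0.0241 for Arc, 0.589 for Egr1, 0.381 for Junb and 0.185 for Nr4a1, and without number 3 it was 0.0577 for Junb and 0.0615 for Nr4a1. Fos passed without a filter (0.398 ± 0.0405 to 1.06 ± 0.0789, 2.65-fold, limma adjusted p = 0.0085), and with the block Npas4 (0.437 ± 0.0608 at 30 min, adjusted p = 0.00325) and Fosb (0.175 ± 0.0269 to 0.399 ± 0.0618, adjusted p = 0.028, but not by voom on the same genes) passed too, which made 7 genes. Lower genes with the smallest unadjusted p, not past the threshold, were the membrane fusion gene Snap23 (1.19 ± 0.124 to 0.957 ± 0.013), Cldn5 (1.32 ± 0.122 to 1.09 ± 0.0855) and the translation kinase gene Mknk1 (1.31 ± 0.101 to 1.13 ± 0.0413).

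The immediate-early list was higher at 30 min in 20 of 21 genes (median log2 change 0.11, camera adjusted p = 8.23e-31), and it held with an estimated correlation (adjusted p = 0.000303, and 0.0106 with the block as well) and in all 6 omissions (largest adjusted p = 1.64e-13). Adjusted over the list alone, 6 of its genes passed, against 0 over all genes. It was 1 of 13 lists called, a count that went to 4 without control replicate 2 and to 6 without 30 min replicate 2. The 1-gene pluripotency list, Sox2, a marker of neural progenitors and astroglia, was lower (3.17 ± 0.247 to 2.76 ± 0.245, -0.15, adjusted p = 0.000678). For 1 gene an estimated correlation (adjusted p = 0.044, and 0.115 with the block as well) is no check, and Sox2 did not pass as a gene. The call ended without control replicate 2 (0.0743) or 30 min replicate 3 (0.0802). Glucocorticoid-responsive genes had a median of 0.06 (adjusted p = 0.000165, and 0.1 with an estimated correlation), including Nfkbia, an inhibitor of NF-kB (1.36 ± 0.258 to 1.71 ± 0.246), and the call ended without control replicate 1 (0.155) or 30 min replicate 2 (0.129). Choroid plexus genes were lower in 11 of 11 (median -0.35, adjusted p = 0.00132). Ttr ran at 1060 ± 827 and 628 ± 447. That list stood at 0.18 (adjusted p = 0.911) without 30 min replicate 3, and its call ended without control replicate 1 (0.799) or 2 (0.654).

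Other lists higher at 30 min were CA1 (0.07, adjusted p = 0.00349), microglia (0.08, 0.00132), inhibitory synapse (0.06, 0.0102), late-response (0.04, 0.0373) and ribosomal protein genes (0.04, 0.00151, 67 of 70 higher). Lower ones were replication-dependent histones, with 4 measured genes (-0.06, 0.0027), endothelial cells and pericytes (-0.04, 0.0316), oxidative phosphorylation (-0.013, 0.0255) and the protein kinase A pathway (-0.02, 0.0256). For these 9 and the choroid plexus, adjusted p = 0.151 to 0.672 with an estimated correlation. Leaving out control replicate 1, 2 or 3 ended 6, 9 and 3 of the 13 calls, and leaving out 30 min replicate 1, 2 or 3 ended 4, 8 and 6. Late-response genes lost the call in all 6 omissions, and oxidative phosphorylation was called higher without 30 min replicate 1 (0.06, adjusted p = 0.0497). The block called 15 lists, adding astrocytes (adjusted p = 0.018) and cholesterol synthesis (adjusted p = 0.0358), both higher and both lost with an estimated correlation (adjusted p = 0.435).

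At 4 h the comparison asks what remains or begins once the early response has passed. Arc and Egr1 footprints stood near their control values. Late-response genes, which encode secreted and synaptic effectors of activity, were higher as a list, as were genes of inhibitory and excitatory synapses, potassium channels and astrocytes, all calls lost with an estimated correlation (adjusted p = 0.333 to 0.47). Ribosomal protein, proteasome and choroid plexus genes carried fewer footprints, calls lost with it as well (adjusted p = 0.513 to 0.524).

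At 4 h limma called 0 of 7898 genes (smallest adjusted p = 1), with 42 at an unadjusted p under 0.05. Voom, the robust fit and the block gave 0 (smallest adjusted p = 0.119 with the block). Arc stood at 4.09 ± 0.407 and Egr1 at 6.45 ± 0.534, against 4.51 ± 0.697 and 6.91 ± 0.651 in control. Bdnf, the gene of a neurotrophin that strengthens synapses, went from 4.32 ± 0.132 to 4.8 ± 0.155, and the immediate-early prostaglandin synthase gene Ptgs2 from 3.79 ± 0.663 to 4.71 ± 0.657. Neither passed. Genes with the smallest unadjusted p, none past the threshold, were the astrocyte connexin gene Gjb6 (4.61 ± 0.43 to 5.66 ± 0.0586), the Wnt inhibitor gene Apcdd1 (1.48 ± 0.126 to 1.84 ± 0.076) and the zinc finger gene Klf6 (1.46 ± 0.0403 to 1.84 ± 0.0665) on the higher side. On the lower side they were the potassium channel subunit gene Kcng1 (2.57 ± 0.111 to 2.18 ± 0.0942), the zinc finger gene Zfp189 (1.05 ± 0.12 to 0.874 ± 0.0339) and the coenzyme Q gene Coq10b (1.92 ± 0.122 to 1.62 ± 0.199).

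Of 37 lists, 14 were called at 4 h (9 without 4 h replicate 2), and 0 with an estimated correlation. Late-response genes (median log2 change 0.07, camera adjusted p = 0.00112) included Nptx2, whose secreted protein gathers AMPA receptors at excitatory synapses (4.44 ± 0.2 to 5.38 ± 0.507). Theirs was the only call kept in all 6 omissions (largest adjusted p = 0.0489, without 4 h replicate 2), and adjusted p = 0.333 with an estimated correlation. Inhibitory synapse genes were higher in 19 of 19 (0.09, adjusted p = 9.43e-06), and ended at adjusted p = 0.584 without control replicate 2. Potassium channel genes were higher in 24 of 24 (0.06, adjusted p = 2.43e-05; 0.148 without 4 h replicate 2), and glutamate receptor and postsynaptic genes in 27 of 30 (0.06, adjusted p = 0.000219; 0.0757 without 4 h replicate 2), such as the NMDA receptor genes Grin1 (63 ± 13.2 to 71.3 ± 8.69) and Grin2a (22.2 ± 2.23 to 25.4 ± 1.97). Astrocyte genes had a median of 0.08 (adjusted p = 0.000188; 0.105 without control replicate 2 and 0.0741 without 4 h replicate 1), among them the growth factor receptor gene Fgfr3 (7.9 ± 0.895 to 9.38 ± 0.421), and microglial genes 0.09 (adjusted p = 0.000194; median -0.02 and adjusted p = 0.488 without control replicate 2). CA1 genes had a median of 0.08 (adjusted p = 0.00518; 0.64 without 4 h replicate 2 and 0.125 without control replicate 2) and CA3 genes 0.08 (adjusted p = 0.0263), a call lost in all omissions but that of control replicate 3. For these 7 lists adjusted p = 0.39 to 0.47 with an estimated correlation.

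Ribosomal protein genes were lower in 67 of 70 at 4 h (median -0.07, camera adjusted p = 1.2e-08; 0.639 without 4 h replicate 1 and 0.0522 without control replicate 3). The proteasome was lower in 30 of 30 (-0.05, adjusted p = 2.43e-05; median 0.02 and adjusted p = 0.775 without 4 h replicate 2). Translation factor genes had a median of -0.03 (adjusted p = 0.0106; 0.02 and 0.977 without 4 h replicate 2, and 0.126 without control replicate 1), including the helicase gene Eif4a2 (32.2 ± 1.43 to 29.7 ± 3.5). Oxidative phosphorylation genes had -0.03 (adjusted p = 0.0055; 0.02 and 0.817 without 4 h replicate 1, 0.711 and 0.285 without control replicate 2 or 3). Mitochondrial ribosomal protein genes had -0.02 (adjusted p = 0.0393; 0.0514 with the block), a call lost without control replicate 2 or 3 or 4 h replicate 1 or 2 (adjusted p = 0.148 to 0.817). Choroid plexus genes were lower in 11 of 11 (-0.52, adjusted p = 0.00112), with Ttr at 617 ± 549 against 1060 ± 827. Without 4 h replicate 3 that list stood at 0.19 (adjusted p = 0.751), and its call ended without control replicate 1 (0.579) or 2 (0.369). For all 6 adjusted p = 0.513 to 0.667 with an estimated correlation. The block called 18 lists, adding dentate granule cell (adjusted p = 0.0455), endothelial (0.00531), glucocorticoid-responsive (0.0234), interneuron (0.00893) and presynaptic genes (0.0131), all higher and all lost with an estimated correlation (adjusted p = 0.429).

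A test across all times asks which footprints moved at any point. The genes it named with the block were the activity-regulated Arc, Egr1, Junb and Nr4a1, the neurite protein gene Nrsn1 and D4Wsu53e, a gene of unassigned function. Limma's F-test called 0 genes without a block (31 at an unadjusted p under 0.05, smallest adjusted p = 0.129; voom and the robust fit gave 0) and 6 with it (smallest adjusted p = 6.42e-05). Leaving out replicate number 1, 2 or 3 gave 1, 38 and 4. When low values were not filtered, it called Fos and Npas4 without a block (smallest adjusted p = 0.000973). Arc, Egr1, Junb and Nr4a1 each peaked at 30 min in the mean, and Npas4 at 10 min.

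**Figure D1:**
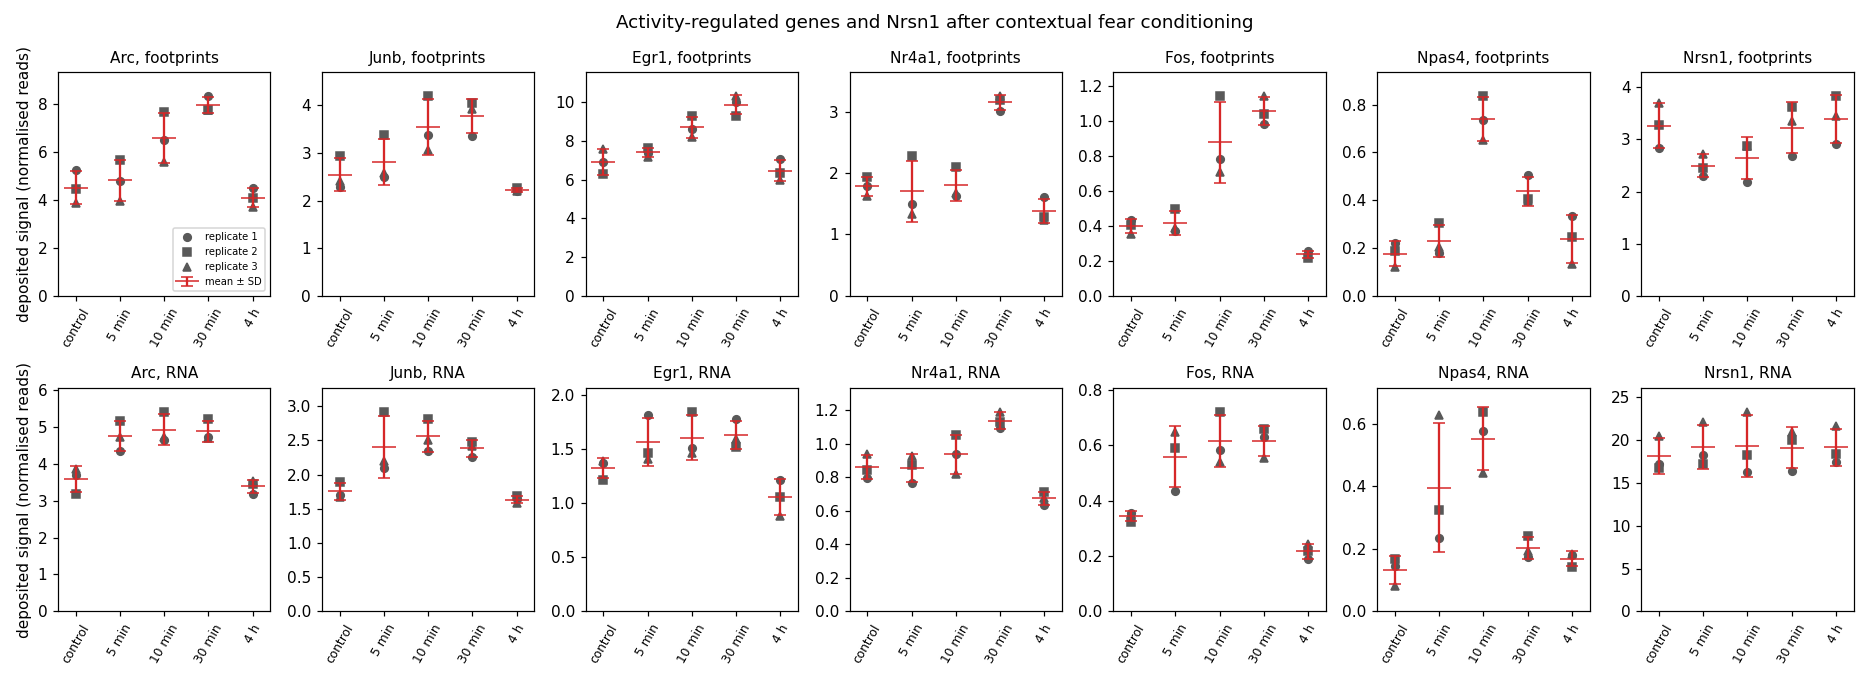
Signal of 7 genes in each tissue library by time after conditioning, footprints above and RNA below, with replicate 1 as circles, 2 as squares and 3 as triangles and the mean ± SD of 3 in red. Arc footprints rise from a mean of 4.51 in control to 7.94 at 30 min while Arc RNA is at 4.74 by 5 min and at 4.87 at 30 min.

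RNA at 5 min was compared with control to ask which transcript levels had already changed. Over all genes the median RNA change was 0.0126, 0.0316, 0.0304 and 0.0269 at 5, 10 and 30 min and 4 h, and camera calls a list against it. The immediate-early list was higher, though not with an estimated correlation and the block (adjusted p = 0.217). With the block, Arc and Junb rose, Arc not with a choroid plexus covariate beside it (adjusted p = 0.0702). Cytosolic ribosomal protein mRNAs were higher as a list and mitochondrial ribosomal protein mRNAs lower, both calls lost with an estimated correlation (adjusted p = 0.901).

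Limma called 0 of 8061 genes in RNA at 5 min (84 at an unadjusted p under 0.05, smallest adjusted p = 1; voom and the robust fit 0), and 3 with the block, 2 by voom with the block. Arc went from 3.58 ± 0.351 to 4.74 ± 0.411 and Junb from 1.75 ± 0.118 to 2.40 ± 0.45 (log2 changes 0.33 and 0.30, limma adjusted p = 0.0235 each with the block). Neither passed without replicate number 1, 2 or 3, with adjusted p = 0.0635 to 0.624. Nrsn1 RNA stood at 18.1 ± 2.08 and 19.2 ± 2.6 (log2 change 0.08, SE 0.14; -0.024 without 5 min replicate 3). Genes with the smallest unadjusted p, not past the threshold, included the phosphodiesterase gene Pde3b (1.84 ± 0.158 to 2.22 ± 0.0461), the tubulin complex gene Mzt2 (1.2 ± 0.0431 to 1 ± 0.00494), the pantothenate kinase family gene Pank4 (1.48 ± 0.0594 to 1.26 ± 0.00324) and the nuclease gene Rexo4 (1.88 ± 0.0322 to 1.64 ± 0.0351). Of 3 lists called, the immediate-early list was higher in 15 of 17 genes (median 0.07, camera adjusted p = 0.000314, 0.0269 with an estimated correlation, and 0.217 with that and the block; 0.0675 without RNA control replicate 1). Ribosomal protein genes were higher in 69 of 73 (0.05, adjusted p = 0.000598; 0.879 without 5 min replicate 3, 0.852 without control replicate 1, 0.333 without 5 min replicate 2). Mitochondrial ribosomal protein genes had -0.03 (adjusted p = 0.00916; 0.702 without 5 min replicate 1, 0.297 and 0.176 without control replicate 2 or 3). For both adjusted p = 0.901 with an estimated correlation. Leaving out control replicate 1 gave 1 list, control replicate 3 gave 7 and any 5 min replicate gave 6. The block called 6, adding choroid plexus (adjusted p = 3.64e-07) and oxidative phosphorylation (0.0111), both lower, and microglia (0.0273), higher, all 3 lost with an estimated correlation (adjusted p = 0.543 to 0.777).

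The RNA comparison at 10 min asks the same for the peak of Npas4 footprints. Arc and Junb RNA rose with the block. The immediate-early list, with Btg2 and the orphan nuclear receptor gene Nr4a2, was higher, though not with an estimated correlation and the block (adjusted p = 0.146). Ribosomal protein mRNAs were again higher as a list, a call lost with an estimated correlation (adjusted p = 0.828).

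In RNA at 10 min limma called 0 of 8061 genes (150 at an unadjusted p under 0.05, smallest adjusted p = 1; voom and the robust fit 0) and 2 with the block and with voom and the block, Arc (4.93 ± 0.424 against 3.58 ± 0.351, adjusted p = 0.00324) and Junb (2.56 ± 0.233 against 1.75 ± 0.118, adjusted p = 0.00118), each with a log2 change of 0.37. Without replicate number 2 Arc had adjusted p = 0.127, and without number 3 Junb had adjusted p = 0.111. With no filter and the block 5 passed, among them Arc, Fos, Junb and Npas4 (0.132 ± 0.0442 to 0.553 ± 0.101, limma adjusted p = 0.00031). Not past the threshold were Btg2 (1.43 ± 0.059 to 1.82 ± 0.192), Nr4a2 (1.66 ± 0.204 to 2.01 ± 0.119), the mRNA export gene Sarnp (2.51 ± 0.174 to 3.05 ± 0.216), the mitophagy kinase gene Pink1 (18.9 ± 0.989 to 16.3 ± 0.524) and Tmem121, which encodes a membrane protein (1.41 ± 0.0227 to 1.22 ± 0.0763). The immediate-early list was higher in 16 of 17 genes (median 0.07, camera adjusted p = 2.98e-05, 0.0125 with an estimated correlation, and 0.146 with that and the block), and it kept the call in all 6 omissions (largest adjusted p = 0.0411, without 10 min replicate 2). Ribosomal protein genes were higher in 73 of 73 (0.08, adjusted p = 0.000179; 0.914 without 10 min replicate 3, where camera's direction turned, 0.791 without control replicate 1 and 0.255 without 10 min replicate 2). Proteasome genes had -0.014 (adjusted p = 0.0142), a call lost without control replicate 1 or 2 or 10 min replicate 2 or 3 (0.154 to 0.615). For both adjusted p = 0.828 with an estimated correlation. Of 37 lists 3 were called, 10 without control replicate 3, 5 without 10 min replicate 3 and 8 with the block, which added inhibitory synapse (0.049), glucocorticoid-responsive (0.049) and potassium channel genes (0.033), higher, and mitochondrial ribosomal protein (0.049) and oxidative phosphorylation genes (0.0191), lower, all 5 lost with an estimated correlation (adjusted p = 0.736).

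At 30 min the RNA comparison sets transcripts beside the footprint peak. Arc and Junb RNA rose with the block, Arc not with a choroid plexus covariate beside it (adjusted p = 0.187). The immediate-early list was higher, though not with an estimated correlation and the block (adjusted p = 0.076). Glucocorticoid-responsive transcripts were higher and choroid plexus transcripts lower as lists, both calls lost with an estimated correlation (adjusted p = 0.699 and 0.964).

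For RNA at 30 min limma called 0 of 8061 genes (118 at an unadjusted p under 0.05, smallest adjusted p = 1; voom and the robust fit 0) and 2 with the block and with voom and the block, Arc (4.87 ± 0.28 against 3.58 ± 0.351, log2 change 0.36, adjusted p = 0.0107) and Junb (2.38 ± 0.116 against 1.75 ± 0.118, 0.30, adjusted p = 0.0177). Without replicate number 1 they had adjusted p = 0.0762 and 0.276, Arc had 0.133 without number 2, and Junb had 0.162 without number 3. With no filter and the block 4 passed, Arc, Junb and Fos (0.344 ± 0.0177 to 0.615 ± 0.0548) up and Cdkn1c, a cell cycle inhibitor gene, down (0.57 ± 0.27 to 0.297 ± 0.143, adjusted p = 0.00409). Egr1 went from 1.33 ± 0.0962 to 1.63 ± 0.133 and Sgk1 from 4.99 ± 0.973 to 6.19 ± 0.642, without passing. The aryl hydrocarbon target gene Tiparp (2.21 ± 0.0611 to 2.76 ± 0.175), Cldn5 (1.57 ± 0.0944 to 1.28 ± 0.109) and Mapk1ip1l, which encodes a kinase-interacting protein (2.55 ± 0.066 to 2.3 ± 0.122), were among the smallest unadjusted p, not past the threshold. Of 4 lists called, the immediate-early list was higher in 15 of 17 genes (median 0.09, camera adjusted p = 1.05e-06, 0.005 with an estimated correlation, and 0.076 with that and the block). It was called in all 6 omissions (largest adjusted p = 0.00806), with 3 genes adjusted over the list alone. Choroid plexus genes were lower in 9 of 9 (-0.38, adjusted p = 0.00228; 0.07 and 0.554 without 30 min replicate 3, 0.347 and 0.702 without control replicate 1 or 2). Glucocorticoid-responsive genes had 0.08 (adjusted p = 0.045; 0.648 without control replicate 1, 0.189 and 0.291 without 30 min replicate 2 or 3) and endothelial genes -0.0034 (adjusted p = 0.045; 0.07 to 0.552 without control replicate 1 or 2 or 30 min replicate 2 or 3). For these 3 adjusted p = 0.964, 0.699 and 0.701 with an estimated correlation. Leaving out control replicate 2 gave 2 lists and control replicate 3 gave 9. The block called 7, adding microglia (0.0238) and inhibitory synapse (0.0238), higher, and oxidative phosphorylation (0.0247), called lower with a median of 0.0016, all 3 lost with an estimated correlation (adjusted p = 0.644 to 0.721).

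RNA at 4 h was compared with control for late changes. Kcnj2, which encodes an inwardly rectifying potassium channel that sets the resting potential, rose with the block. Choroid plexus transcripts were lower and inhibitory synapse transcripts higher as lists, both calls lost with an estimated correlation (adjusted p = 0.864) or without control replicate 2.

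Limma called 0 of 8061 genes in RNA at 4 h (209 at an unadjusted p under 0.05, smallest adjusted p = 1; voom and the robust fit 0) and 1 with the block and with voom and the block. Kcnj2 went from 1.72 ± 0.157 to 2.47 ± 0.232 (log2 change 0.35, SE 0.08; fold 1.32 to 1.58 in the 3 numbers, limma adjusted p = 0.00107 with the block), and it passed without each replicate number (largest adjusted p = 0.0414), but not with a choroid plexus covariate beside the block (adjusted p = 0.197). With no filter and the block 4 passed: Kcnj2 and the Rac activator gene Prex2 (14.2 ± 2.27 to 16.7 ± 1.66, adjusted p = 0.0395) up, and the choroid plexus water channel gene Aqp1 (1.68 ± 1.28 to 0.893 ± 0.937, adjusted p = 0.0434) and the calmodulin-like gene Calml4 (0.836 ± 0.533 to 0.465 ± 0.398, adjusted p = 0.0395) down. Bdnf (3.67 ± 0.206 to 4.1 ± 0.316) did not pass, nor did the genes with the smallest unadjusted p, such as the Wnt signalling gene Daam2 (2.78 ± 0.0374 to 3.3 ± 0.122, adjusted p = 0.0693 with the block), the centrosome gene Pibf1 (1.75 ± 0.146 to 2.11 ± 0.0709) and the apoptosis gene Bad (1.77 ± 0.152 to 1.45 ± 0.0355). Of 37 lists 4 were called, 0 with an estimated correlation, 0 without control replicate 2 and 2 without 4 h replicate 3. Choroid plexus genes were lower in 9 of 9 (-0.47, camera adjusted p = 0.00652; 0.07 and 0.797 without 4 h replicate 3, 0.343 and 0.53 without control replicate 1 or 2), with Ttr at 215 ± 200 against 382 ± 295. Inhibitory synapse genes had 0.12 (adjusted p = 0.0285; 0.53, 0.255 and 0.053 without control replicate 2, 4 h replicate 1 or 4 h replicate 3). Oxidative phosphorylation genes had -0.013 (adjusted p = 0.00986; 0.53, 0.255 and 0.0936 without control replicate 2, 4 h replicate 1 or 2) and mitochondrial ribosomal protein genes -0.016 (adjusted p = 0.0485; 0.53, 0.251, 0.317 and 0.177 without control replicate 2 or 3 or 4 h replicate 1 or 2). For all 4 adjusted p = 0.864 with an estimated correlation. The block called 5, adding astrocytes (0.0338), higher, lost with an estimated correlation (adjusted p = 0.754).

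**Figure D2:**
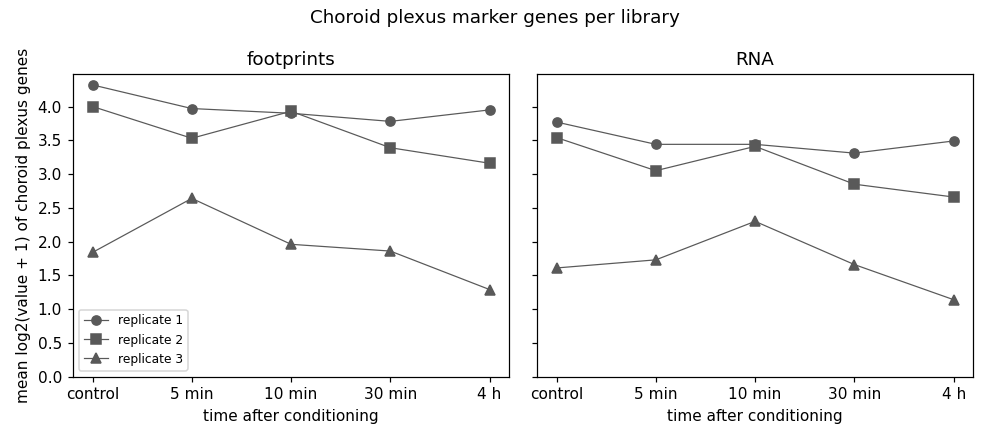
Mean log2(signal + 1) of choroid plexus genes in each tissue library, for footprints and RNA, with lines that join libraries of 1 replicate number across times. In footprints replicate 3 stands at 1.84 in control, below 4.32 and 4.00 in replicates 1 and 2, and the 4 h values are 3.95, 3.16 and 1.29.

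Across all times, the genes that the RNA test called with the block included the activity-regulated genes Arc, Egr1 and Junb and the channel gene Kcnj2. Limma's F-test called 0 genes without a block (44 at an unadjusted p under 0.05, smallest adjusted p = 0.274; voom and the robust fit 0) and 5 with it (smallest adjusted p = 3.26e-05). Leaving out replicate number 1, 2 or 3 gave 24, 5 and 8. Fos passed without a filter or a block (adjusted p = 0.0217).

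Translational efficiency asks whether footprints moved more or less than the RNA of the same gene. At 5 min ribosomal protein and proteasome genes were lower in TE as lists, both calls lost with an estimated correlation (adjusted p = 0.972). Cnot7, which encodes a deadenylase that shortens mRNA tails, was lower with the block.

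At 5 min limma called 0 of 7103 genes in TE (50 at an unadjusted p under 0.05, smallest adjusted p = 1; voom and the robust fit 0), 1 with the block and 0 by voom with the block. Cnot7 had a log2 change of -0.29 (SE 0.099, adjusted p = 0.0486 with the replicate block), but adjusted p = 1 with RPF and RNA pairs as the block and 0.115 to 1 without replicate number 1, 2 or 3. Log2 changes of TE were -0.28 for Mapk6 (SE 0.068), -0.26 for Hdac5, -0.21 for the chaperone gene Ric8b, 0.26 for the hypoxia factor gene Epas1, 0.25 for Smpd1, 0.15 for the mitochondrial assembly gene Ndufaf7 and -0.36 for Nrsn1 (SE 0.18), none past the threshold. Of 2 lists called, ribosomal protein genes were lower in 64 of 70 (median -0.09, camera adjusted p = 6.01e-05), among them Rps24 (-0.25), Rplp0 (-0.18) and Rpl14 (-0.17), and stood at -0.01 (adjusted p = 0.93) without RPF 5 min replicate 1. That call also ended without RPF control replicate 3 (0.194), RNA control replicate 1 (0.479) or RNA 5 min replicate 2 (0.114) or 3 (0.425). Proteasome genes were lower in 29 of 30 (-0.06, adjusted p = 0.0189), a call lost without RPF control replicate 2 or 3, RNA control replicate 3, RPF 5 min replicate 1 or 2 or RNA 5 min replicate 3 (0.0594 to 0.536). For both adjusted p = 0.972 with an estimated correlation. The number of lists ran from 0 without RPF control replicate 3 to 8 without RPF control replicate 1, with 5 and 6 without RPF 5 min replicate 2 and RNA 5 min replicate 1, and 1 without RPF control replicate 2, RNA control replicate 1 or RNA 5 min replicate 2 or 3. The block called 3, adding choroid plexus genes (adjusted p = 0.0349), higher, lost with an estimated correlation (adjusted p = 0.813).

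At 10 min no list was called in TE. Pink1, the mitophagy kinase gene, and Amd1, a polyamine synthesis gene, were among the higher genes, and the zinc finger genes Zfp592 and Zfp106 among the lower, without passing. Limma called 0 of 7103 genes (58 at an unadjusted p under 0.05, smallest adjusted p = 1; voom, the robust fit and the block 0). Their log2 changes were 0.24, 0.17, -0.23 and -0.24, beside 0.15 for the T-complex family gene Tcp11l1 and -0.28 for Mapk6. Of 37 lists 0 were called, and 0 with the block, but leaving out RPF control replicate 1, 2 or 3 gave 3, 3 and 6, RNA control replicate 1 or 2 gave 1 and 2, RPF 10 min replicate 1 or 3 gave 3 and 2, and RNA 10 min replicate 1 or 3 gave 1 and 2.

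The 30 min TE comparison asks whether immediate-early mRNAs gained more ribosomes than their RNA level gives. Arc and Egr1 had the larger positive values among activity-regulated genes but did not pass. The immediate-early list was called higher although many of its members were lower, and ribosomal protein genes were higher as a list. The first call was lost with an estimated correlation and the block (adjusted p = 0.373), the second with an estimated correlation alone (adjusted p = 0.978). Limma called 0 of 7103 genes (16 at an unadjusted p under 0.05, smallest adjusted p = 1; voom, the robust fit and the block 0). Arc had a TE log2 change of 0.34 (SE 0.15) and Egr1 of 0.28 (SE 0.11). The smallest unadjusted p also included Banp, a chromatin regulator gene (0.14), the DNA repair gene Nbn (-0.17), the transcription repressor gene Mier3 (-0.20) and the sorting nexin gene Snx7 (-0.16), none past the threshold. Immediate-early genes were higher in 9 and lower in 7 of 16 (median 0.02, mean 0.06, camera adjusted p = 0.000111, 0.0298 with an estimated correlation, and 0.373 with that and the block), and kept the call without any 1 of the 12 libraries (largest adjusted p = 0.0116). With a filter at 5 it had a median of -0.05 (adjusted p = 0.733). Ribosomal protein genes had a median of 0.03 (adjusted p = 0.000509, and 0.978 with an estimated correlation), a call lost without RPF control replicate 1 (median -0.03, adjusted p = 0.847), RNA control replicate 3 (0.829), RPF 30 min replicate 2 (0.183) or 3 (0.751) or RNA 30 min replicate 1 (0.688). The 2 lists called became 4 without RPF control replicate 3, RPF 30 min replicate 1 or RNA 30 min replicate 2, and 1 without RNA 30 min replicate 1.

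At 4 h ribosomal protein and translation factor genes were lower in TE as lists, both calls lost with an estimated correlation (adjusted p = 0.906). The lipoprotein receptor gene Scarb1, the oxygen sensor gene Egln2 and the transcription factor gene Foxj2 had the smallest unadjusted p among higher genes. Among lower ones were Sarnp, the deubiquitinase gene Brcc3 and 1700021F05Rik, a gene of unassigned function. Limma called 0 of 7103 genes (44 at an unadjusted p under 0.05, smallest adjusted p = 1; voom, the robust fit and the block 0), and these 6 had log2 changes of 0.21, 0.24, 0.19, -0.24, -0.23 and -0.25. Ribosomal protein genes were lower in 64 of 70 (median -0.10, camera adjusted p = 2.01e-06), with -0.24 for Rpl39 and for Rps27a, a call lost without RPF control replicate 3 (0.0871), RNA control replicate 1 (0.176), RPF 4 h replicate 1 (0.664) or RNA 4 h replicate 2 (0.563). Translation factor genes had -0.06 (adjusted p = 0.0141), with -0.20 for Eif4a2 and -0.19 for the initiation factor gene Eif1ax, a call lost without RPF control replicate 1 (0.0627) or 2 (0.165), RNA control replicate 1 (0.176), RPF 4 h replicate 2 (0.712) or RNA 4 h replicate 3 (0.172). The 2 lists called became 0 without RNA control replicate 1, 1 without RPF control replicate 2, RPF 4 h replicate 1 or 2 or RNA 4 h replicate 3, 4 without RPF control replicate 1, 5 without RNA control replicate 2 and 6 without RPF 4 h replicate 3.

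Across the transcriptome, changes of footprints correlated with changes of RNA, but at each time as strongly after time and control labels were exchanged in at least 1 replicate number. Over 7103 genes Pearson's r between the RPF and RNA log2 changes was 0.226, 0.273, 0.42 and 0.455 at 5, 10 and 30 min and 4 h, and Spearman's rho was 0.218, 0.254, 0.28 and 0.306. With the labels of number 1, 2 or 3 exchanged in both kinds of library, r was 0.0931, 0.131 and 0.514 at 5 min, 0.375, 0.0794 and 0.361 at 10 min, 0.364, 0.628 and 0.654 at 30 min and 0.549, 0.528 and 0.477 at 4 h. Genes are not independent replicates.

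In unconditioned tissue, baseline TE asks which genes have many or few footprints for their RNA signal, and whether brain tissue, primary culture and ESC differ in it. Ribosomal protein mRNAs, many of which bear the pyrimidine-rich start that couples their translation to growth signals, had low TE in the hippocampus, less so in culture and least in ESC. Presynaptic, oxidative phosphorylation, proteasome and chaperone genes had high TE in tissue. TE is relative to the median gene of its own table, and tables were scaled separately, so levels set across them were not tested. Ribosomal protein genes with near-identical copies are uncertain.

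The ribosomal protein list had a median TE of -0.943 ± 0.112 (SD, n = 3 control replicates), below every one of 10000 random lists (percentile 0). In culture it was -0.715 (95% counting interval -0.754 to -0.689; percentile 0; 60 of 69 genes below 0) and in ESC -0.249 (-0.263 to -0.234; percentile 0.07; 47 of 76 below 0). Of 68 genes measured in all 3 sources, 56 were lower in tissue than in ESC, 47 lower in tissue than in culture and 55 lower in culture than in ESC. The lowest in tissue were Rpl13a (-2.40 ± 0.0493), Rps12 (-2.20 ± 0.186), Rps3a1 (-2.09 ± 0.0872), Rpl41 (-2.04 ± 0.18) and Rpl5 (-1.91 ± 0.0833), components of both ribosomal subunits. The highest was Rps16 (1.23 ± 0.27). Translation factor genes were split, with a median of -0.04 ± 0.0338: the start codon selection factor gene Eif1 stood at 2.46 ± 0.136 and the neuronal elongation factor gene Eef1a2 at 1.64 ± 0.0902, but Eif4b, a helicase cofactor gene, at -2.12 ± 0.17, and the elongation factor genes Eef1g and Eef1a1 at -1.55 ± 0.101 and -1.05 ± 0.05.

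Presynaptic genes had a median TE of 0.82 ± 0.0125 in tissue and 0.68 in culture. The vesicle genes Syn1 (2.63 ± 0.127) and Vamp2 (1.97 ± 0.0907) were high, and the active zone scaffold genes Rims1 (-1.84 ± 0.0709) and Rims2 (-2.25 ± 0.0866) low. Oxidative phosphorylation genes had 0.80 ± 0.124 in tissue, 0.36 in culture and 0.27 in ESC, led in tissue by the complex III gene Uqcrq (2.38 ± 0.682) and the ATP synthase gene Atp5g3 (1.92 ± 0.0929). Proteasome genes had 0.73 ± 0.063, 0.52 and 0.53, and heat shock and chaperone genes 0.77 ± 0.0319, 0.72 and 0.57, led by the disulfide isomerase gene Pdia3 (2.51 ± 0.203). Protein kinase A and CREB pathway genes had -0.31 ± 0.0233, -0.49 and -0.18, and potassium channel genes -0.13 ± 0.0705 in tissue and -0.51 in culture, both within the range of random lists in tissue and below it in culture (percentiles 1.32 and 0.11).

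**Figure D3:**
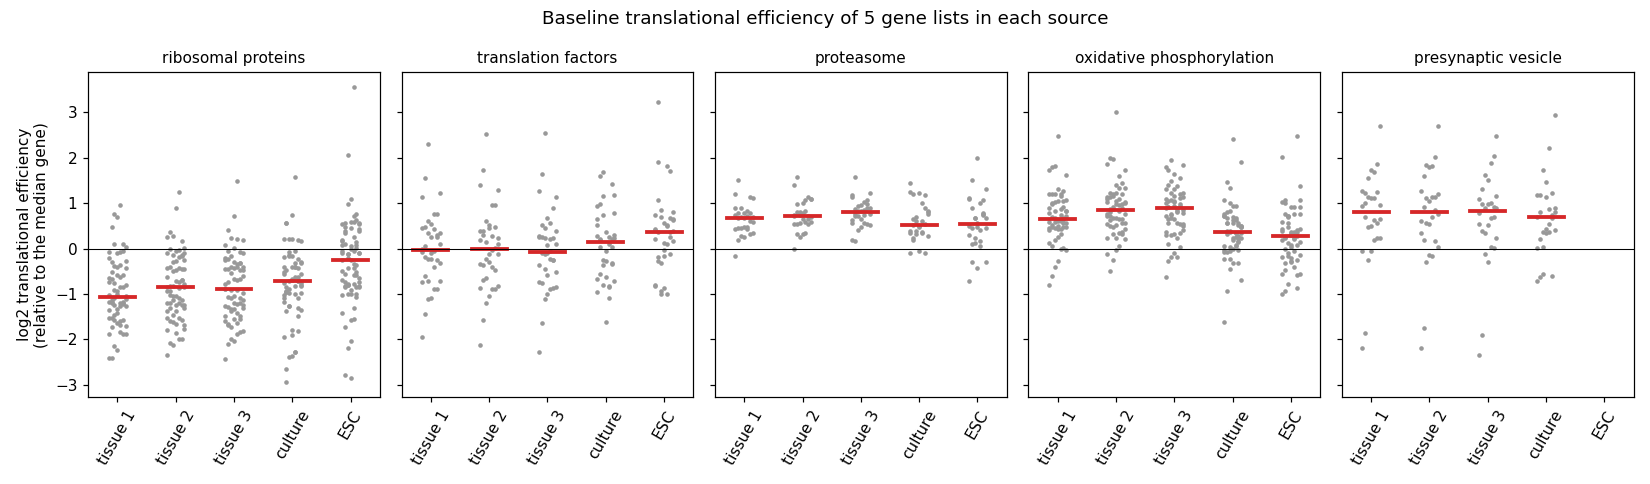
Baseline TE of genes (points) in 5 lists with the list median (red), in control tissue replicates 1 to 3, primary culture and ESC, as log2 of footprints over RNA relative to the median gene of each sample. Ribosomal protein genes have a mean median of -0.943 in tissue and medians of -0.715 and -0.249 in culture and ESC, and the presynaptic list has no ESC points because fewer than 3 of its genes were measured there.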

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

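Tests of differences between times and every test of an explanation given here were chosen only after the result was seen, except the correlation of choroid plexus scores between RPF and RNA libraries. Counts over other splits were also read after the result.

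Activity-regulated genes differed between times after conditioning. Differences were tested in limma with the replicate block (Benjamini-Hochberg adjusted p over all genes of a pair of times). In footprints, Nr4a1 and Arc were higher at 30 min than at 5 min (log2 differences 0.636 and 0.633, adjusted p = 0.00127 and 0.000907), and Nr4a1 higher at 30 than at 10 min (0.572, adjusted p = 0.0106). From 10 min to 4 h, Arc (-0.567, adjusted p = 0.00211), Junb (-0.484, 0.00196) and Egr1 (-0.38, 0.0216) fell and Klf6 rose (0.222, 0.0216), among 7 genes that differed. From 30 min to 4 h, Arc (-0.816, adjusted p = 2.1e-05), Nr4a1 (-0.803, 4.41e-05), Junb (-0.56, 8.21e-05) and Egr1 (-0.545, 0.000238) fell. Without the block, only Arc, Egr1 and Nr4a1 passed, from 30 min to 4 h in footprints.

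In RNA, from 5 min to 4 h Arc (-0.387, adjusted p = 0.00111), Junb (-0.36, 0.00111) and Egr1 (-0.32, 0.023) fell and Kcnj2 rose (0.327, 0.00111). From 10 min to 4 h Arc (-0.433, adjusted p = 0.000253), Junb (-0.431, 7.48e-05) and Egr1 (-0.344, 0.00811) fell and Kcnj2 rose (0.288, 0.00811). From 30 min to 4 h Arc (-0.421, adjusted p = 0.000812), Junb (-0.36, 0.000909) and Egr1 (-0.356, 0.0049) fell and Kcnj2 rose (0.305, 0.00346). None passed in RNA without the block. From 10 min to 4 h 11 genes differed in RNA, only Kcnj2 higher, and among the lower ones were choroid plexus genes such as Enpp2, so transcripts of another tissue moved too.

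Choroid plexus genes were lower at 30 min and 4 h in both kinds of library. Unequal amounts of this tissue in the dissected samples remain open. Over all times, an exact permutation within replicate numbers gave p = 0.203 for the RPF score, which does not decide this. With the block, no filter and adjustment over the list alone, 4 of 6 genes of ependymal cilia, another ventricle lining, were lower in RPF at 4 h (0 over all genes), which does not tell tissue from conditioning. A change made separately in footprint and RNA libraries would leave the paired scores unrelated: with time and number means removed, Pearson's r was 0.627 (permutation p = 0.012) and Spearman's rho 0.761 (permutation p = 0.0015) over 15 pairs, 0.625 without the 2 farthest, short of the 0.7 set in advance to exclude it. An effect of conditioning remains open too, since the score fell in 5 of 6 comparisons within replicate numbers (mean change -0.376 ± 0.346 at 30 min and -0.584 ± 0.238 at 4 h, SD, n = 3). These explanations cannot be told apart with 3 replicates.

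Ribosomal protein genes were lower in TE in tissue than in ESC. Reads shared with near-identical copies remain open: the median difference of ESC minus tissue over the genes (0.588) only restates the pattern. How such reads were counted is not given. On genes passing in all 3 sources the difference of the list medians was 0.742, which argues against different genes behind each median. A difference between the sources themselves remains open, as the nearest of culture and ESC lay 0.143 above the highest tissue replicate, with 1 library of each kind per cell source, and it cannot be told apart from differences in library preparation.

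Nrsn1 footprints were lower at 5 min, by a change that did not pass. Lower Nrsn1 RNA is not excluded: its change was 0.0775 (-0.024 to 0.16 with single libraries left out), against -0.29 in footprints, but the TE change did not pass. The median change (-0.00475) cannot judge a shift of all footprints, since libraries were scaled. An effect of conditioning stays open and untested.

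Other splits of the 6 libraries per comparison (10 without a block, some uneven in replicate numbers, and 4 with it) are too few for a share under 0.05. For lists called, the real and the highest other counts were 5 and 11, 12 and 11, 13 and 13, and 14 and 11 in RPF at 5, 10 and 30 min and 4 h, with 6, 1, 2 and 1 splits as large, the real one included. In RNA they were 3 and 10, 3 and 7, 4 and 8, and 4 and 7 (9, 8, 5 and 4 splits), and in TE 2 and 6, 0 and 3, 2 and 3, and 2 and 4 (2, 10, 7 and 6). For genes without a block the real count was 0, which any split reaches, and the highest other 0, or 1 in RNA at 4 h. With the block the real counts were 0, 0, 4 and 0 in RPF (4, 4, 1 and 4 splits as large), 3, 2, 2 and 1 in RNA (1 each) and 1, 0, 0 and 0 in TE (1, 4, 4 and 4), and the highest other was 0, or 1 in RPF at 10 min.

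With the block, chance cannot be excluded across all times. In RPF 7 of 100 splits gave as many genes as the 6 (highest other 353), and in RNA 7 of 100 as many as the 5 (highest other 25). Without the block any split reaches the real 0 and may be uneven, so chance is not tested (highest others 3266 in RPF and 2228 in RNA).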

How the results depend on the processing

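The settings that combine the replicate block with another choice, all fits with voom, the choroid plexus covariate, the minimum of 3 list members and the alternatives of list counts were chosen only after the data were seen. Where no reason is given for a change below, the cause was not tested.

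The immediate-early list in RPF at 30 min kept its call under every setting run for it, with the largest adjusted p = 0.0106 under the estimated correlation with the block. Of the values of named genes under settings that keep every library, 1723 kept their direction and side of the threshold, 107 came past the threshold and 2 changed direction. Of the called lists' values, 291 kept theirs, 149 kept the direction but lost the call and 2 changed direction. Of the counts, correlations and baseline medians, 227 stayed within the limits set for them and 96 moved.

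Arc, Egr1, Junb and Nr4a1 footprints at 30 min passed with the block and with the block beside voom, a pseudocount of 0.1, median centring or the choroid plexus covariate, against 0 genes without a block. Without a filter, 1 gene was called in RPF at 10 min and 1 at 30 min, and 2 in RPF and 1 in RNA across all times. With no filter and the block, the counts were 5 and 7 in RPF at 10 and 30 min, 10 across all times, 3, 5, 4 and 4 in RNA at 5, 10 and 30 min and 4 h, and 19 across all times. With voom, no filter and the block they were 5, 6 and 9 in RPF and 4, 5, 4, 1 and 10 in RNA. The low genes Fos and Npas4 have a mean under 1, so the filter itself keeps them out of the test.

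The replicate block gave 0, 0, 4 and 0 genes in RPF at 5, 10 and 30 min and 4 h and 6 across all times, 3, 2, 2 and 1 in RNA and 5 across all times, and 1 in TE at 5 min. Voom with the block gave 2, 4 and 6 in RPF at 10 min, 30 min and across all times, and 2, 2, 2, 1 and 5 in RNA. A pseudocount of 0.1 with the block gave 4 at 30 min and 6 across all times in RPF, 3, 2, 2, 1 and 5 in RNA, and 1 in TE at 5 min. Median centring with the block gave 4 and 6 in RPF, and 2, 3, 1, 1 and 5 in RNA. The choroid plexus covariate with the block gave 4 and 5 in RPF, and 1, 2 and 1 in RNA at 5, 10 and 30 min and 5 across all times. Lists called with the block were 8 in RPF at 5 min and 6, 8 and 7 in RNA at 5, 10 and 30 min. Beyond these and the list calls given with each comparison, the block changed no other call.

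With the block, leaving out replicate number 1 gave 1 gene in RPF at 30 min and 1 across all times, and 2, 16 and 24 in RNA at 10 min, 4 h and across all times. Leaving out number 2 gave 2, 12, 6 and 2 in RPF at 5, 10 and 30 min and 4 h and 38 across all times, 2, 1, 1 and 5 in RNA at 10 min, 30 min, 4 h and across all times, and 2 in TE at 30 min. Leaving out number 3 gave 2 in RPF at 30 min and 4 across all times, and 1, 13, 18 and 8 in RNA at 10 min, 30 min, 4 h and across all times.

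With an estimated correlation, the lists called were 0, 0, 2 (1 of them with 1 gene) and 0 in RPF, 1, 1, 1 and 0 in RNA, and 0, 0, 1 and 0 in TE. With the block as well, only the immediate-early list in RPF at 30 min was called, and 0 in every other comparison. These settings widen the null spread of a list whose genes move together.

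A filter at 5 gave 5 lists in RPF at 10 min, 1 and 2 in RNA at 30 min and 4 h, and 1 in TE at 5 min and 1 at 30 min. Under it the endothelial list in RPF at 30 min turned to 0.0651 (camera adjusted p = 0.448) and the immediate-early list in TE at 30 min to -0.052 (adjusted p = 0.733). Median centring gave 8 lists in RPF at 5 min and 2 in RNA at 30 min, and turned the TE change of Bdnf at 30 min to 0.006117, with the block as well. A pseudocount of 0.1 gave 1 list in TE at 5 min. It moved the baseline TE of ribosomal protein genes to -0.295 in ESC and -0.807 in culture, a filter at 5 moved it to -0.339 and -0.814, and the genes passing in all 3 sources gave -0.233 in ESC.

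Leaving out single libraries moved the number of lists called from 3 (without control replicate 2) to 11 (without control replicate 1) in RPF at 5 min, from 7 (control replicate 2) to 10 at 10 min, from 4 (control replicate 2) to 13 at 30 min and from 9 (4 h replicate 2) to 15 at 4 h. In RNA it ran from 1 (control replicate 1) to 7 (control replicate 3), from 2 to 10 (control replicate 3), from 2 (control replicate 2) to 9 (control replicate 3) and from 0 (control replicate 2) to 6. In TE it ran from 0 (RPF control replicate 3) to 8 (RPF control replicate 1), from 0 to 6 (RPF control replicate 3), from 1 (RNA 30 min replicate 1) to 4 and from 0 (RNA control replicate 1) to 6 (RPF 4 h replicate 3). Genes across all times in RPF ran from 0 to 1 (without 5 min replicate 2).

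The median changes of lists that turned, by the direction of the camera test, ranged as follows. Ribosomal protein genes ranged from -0.0021 to 0.105 and from 0.027 to 0.148 in RNA at 5 and 10 min, from -0.047 to 0.129 and from -0.0106 to 0.116 in RPF at 10 and 30 min, and from -0.147 to -0.0112 and from -0.0302 to 0.0972 in TE at 5 and 30 min. Mitochondrial ribosomal protein genes ranged from -0.0662 to 0.00735 in RNA at 5 min and from -0.0654 to 0.017 in RPF at 4 h. Endothelial genes ranged from -0.103 to 0.0882 and from -0.0966 to 0.0899 in RPF at 10 and 30 min, and microglial genes from -0.041 to 0.139 and from -0.0341 to 0.127. Oxidative phosphorylation genes ranged from -0.0678 to 0.0579 and from -0.0815 to 0.0185 in RPF at 30 min and 4 h, and inhibitory synapse genes from -0.0225 to 0.163 and from -0.0279 to 0.124 at 5 and 30 min. At 4 h in RPF, translation factor genes ranged from -0.0914 to 0.0187, proteasome genes from -0.092 to 0.0166, and choroid plexus genes from -1.39 (without control replicate 3) to 0.193 (without 4 h replicate 3).

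Among named genes, none of which had passed in these comparisons, Nrsn1 ranged from -0.02397 to 0.1649 and from -0.01292 to 0.1604 in RNA at 5 min and 4 h and from -0.189 to 0.006618 in TE at 30 min. Bdnf ranged from -0.07953 to 0.02252 in TE at 30 min, and Sgk1 from -0.00104 to 0.2266 and from -0.1943 to 0.05739 in TE at 10 min and 4 h. The correlation of RPF with RNA changes ranged over replicate numbers left out from 0.0959 to 0.471 at 5 min, from -0.00503 to 0.472 at 10 min and from 0.356 to 0.653 at 30 min. With libraries left out, 204 counts, correlations and medians stayed within their limits, 74 moved and 1 changed sign. Of list values 247 kept their call, 149 lost it and 24 turned, and of gene values 1215 kept theirs, 27 came past the threshold and 15 turned.

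Of simulated genes in RPF at 30 min, the test without a block found 64% at 1.5-fold and 10% at the smallest fold. It would mostly miss small changes of genes. With the block it found 94 and 74%.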

Other observations

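The exact tests of list scores and the comparison of replicate numbers were chosen only after the data were seen.

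Several kinds of genes that learning and its tissue context could have moved were called in no comparison of tissue over time. These were lists of excitatory neurons, interneurons, presynaptic vesicles, oligodendrocyte precursors, heat shock proteins, the integrated stress response, mTOR regulation, the circadian clock, cholesterol synthesis, estrogen receptor signalling, blood, meninges, and the neighbouring neocortex, striatum and thalamus. Their smallest camera adjusted p over 12 comparisons were, in that order, 0.171, 0.0513, 0.0727, 0.411, 0.135, 0.326, 0.139, 0.351, 0.0504, 0.469, 0.24, 0.262, 0.0914, 0.241 and 0.134. The list of ependymal cilia had no gene past the filter. Without a filter and with the block, adjusted over the list alone, 4 of its 6 genes were lower in RPF at 4 h and 2 in RNA at 30 min and at 4 h, against 0 without the block. The block called interneurons, presynaptic vesicles and cholesterol synthesis as given for RPF at 4 h and 30 min.

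The immediate-early list was also scored per library, as the mean of its genes, and tested over all times by an exact permutation of times within replicate numbers (14400 arrangements, smallest possible p = 6.9e-05). It gave exact p = 0.00326 in RPF, 0.00181 in RNA and 0.00722 in TE, and Benjamini-Hochberg adjusted p = 0.121, 0.067 and 0.267 over the lists. Ribosomal protein genes had exact p = 0.00833 in RPF (adjusted p = 0.154), and choroid plexus genes 0.203 in RPF and 0.101 in RNA. No list passed after adjustment.

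In replicates 1, 2 and 3, meningeal and fibroblast genes had mean log2(signal + 1) of 3.16, 2.93 and 2.76 in RPF and 2.8, 2.57 and 2.44 in RNA. Ribosomal protein genes ran the other way in RPF, at 3.25, 3.4 and 3.51.

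Baseline TE of other lists in control tissue, as mean ± SD of 3, was high for choroid plexus (0.997 ± 0.25, on 3 genes in replicate 3 and 14 in the others), excitatory neuron (0.83 ± 0.0833), meningeal (0.80 ± 0.0692), microglial (0.74 ± 0.0424), oligodendrocyte (0.72 ± 0.0671) and cholesterol synthesis genes (0.59 ± 0.0869). Estrogen receptor signalling genes had -0.39 ± 0.0624, within the range of random lists (percentiles 8.9 to 16.6), with -0.05 in culture and 0.11 in ESC.

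Of the genes fixed in advance, Esr1, Egr2 and Egr4 have no values among the 11531 genes listed for tissue and were not analysed. Fkbp5, a chaperone gene induced by glucocorticoids, stood at 2.41 ± 0.0887 in control and 2.37 ± 0.0326 at 30 min in RPF.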
